A study of Homo sapiens with 18 samples.

How the data were processed

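Total RNA from 18 Matrigel cultures was hybridised to Illumina BeadChips, 12 arrays of HT29 and 6 of Colo-205, on 2 BeadChips that each held 1 cell line. Groups were taken from the sample labels: cell line, treatment (3 µM PLX4720 or DMSO) and day. HT29 had 2 arrays in each of 6 groups, which the series design describes as biological replicates, and Colo-205 had 1 array per group. Per the labels, the medium held the inhibitor or DMSO from culture day 5.

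The deposited non-normalized table held, per the file headers, 1 linear intensity and 1 detection p-value for each of 47323 probes and each array. No step of background correction by the authors was recorded for this table. How the authors computed the detection p-value is not given in the sources used here, and it was read as a test of a probe's intensity against the array's background. The header of the intensity column for the first PLX4720 replicate of HT29 day 8 carried the word mean. It was used as a single array, and whether it is an average is unknown. Its pair had the highest correlation (0.991) and lowest SD of the difference (0.30) of the 6. The authors' second table held processed intensity values on a linear scale, and how they were normalized is not given in the sources used here. On the log2 scale these values correlated with the raw intensities of the same array at 0.9996 to 1.000, and they were used as an alternative. Every value column was matched to a sample by its name, 0 columns stayed unmapped, and 4 probes with a missing value were left out.

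Intensities were processed with limma 3.58.1 in R 4.3.3. The table held no negative controls, so each array's background mean and SD were inferred from the detection p-values. The background mean lay between 90.3 and 93.2 for Colo-205 and between 99.0 and 103 for HT29. The detection p-values were not exact ranks of the intensities (Spearman -0.990 to -0.988), and a normexp fit that does not use them was added as an alternative after the data were seen. The normexp correction with an offset of 16 was followed by quantile normalization over all 18 arrays and log2. The background correction enlarges fold changes of dim probes and the offset pulls them towards 0, and folds without the correction were smaller. Between 38.3% and 41.4% of the probes of an array had a detection p under 0.01. Probes entered a fit when they had a detection p under 0.01 on at least 2 of its arrays.

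Probes were named from the platform's annotation table, with symbols updated through Entrez identifiers to the RefSeq gene table of GRCh38.p14, in which 99.8% of named probes were found. Of all probes, 30111 had 1 symbol, 8 had several, 17200 had no symbol listed, and 20044 different symbols were named. Each gene was represented by its probe with the highest mean log2 value over the arrays of the fit. Probes with several symbols or none were not used for named genes. Of the 431 genes in the lists, 398 had a named probe, and the other 33 were not analysed here. Of 25 genes fixed by name, 2 had no named probe and were not analysed here, and MUC2 did not pass the filter.

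The HT29 comparisons came from 1 limma fit of 6 group means over 12 arrays with 12675 genes: PLX4720 minus DMSO at days 1, 3 and 8, their mean, the difference between the day 8 and day 1 effects, and the change from day 1 to day 8 in DMSO. The Colo-205 comparison was a fit with day as a block over 6 arrays and 11575 genes, in which the days stood in as replicates of the treatment effect. The line difference was a treatment-by-line term in a fit of 18 arrays and 13659 genes with a baseline for each line and day. All used lmFit and eBayes with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. The tests are two-sided. Pairs of arrays in the report are HT29 arrays with the same day and replicate number, used only to count directions.

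Before the data were examined, 23 gene lists were written down: MAPK output, enterocyte differentiation, goblet cell, enteroendocrine cell, stem cell and Wnt targets, epithelial junctions, mesenchymal and invasion, cell cycle, CDK inhibitors, apoptosis regulators, cholesterol synthesis, glycolysis, hypoxia response, mitochondrial respiration, receptor tyrosine kinases and adaptors, EGF family ligands, interferon response, MHC class I, NF-kB and chemokines, ER and amino acid stress, ribosome biogenesis and MYC targets, non-epithelial cell markers and reference genes. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 63 list results past the threshold at the preset correlation, 23 held with an estimated correlation. That version also allows for the small number of arrays, so a loss need not mean correlated genes. At HT29 day 1, the ribosome list's estimated correlation of -0.00365 was below the preset one, yet its camera p went from 7.55e-16 to 0.000125. In Colo-205, all 7 calls were lost. With fry, another limma list test, 56 of the 63 kept direction and threshold and 7 kept only the direction. The enteroendocrine list had 1 measured gene in Colo-205 and was not tested there. The designs, the alternatives and the rule for named genes were also fixed before the data were examined. The rule took the 5 highest and 5 lowest log2 changes past the threshold with the same direction in every pair of arrays or at every day, up to 4 members of each list, and the 25 fixed genes, and the text names a part of those.

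A probe with a detection p of 0.01 or more on every array of a group was called not above background there, and a gene only if all its probes were. Its fold is then the mean of the bright group against, per array of the dim group, the higher of its own value and the lowest normalized value among probes above background, and is written as at least that size. With such members held at their bound, and members below background in both groups left out, list medians past the threshold in the 6 comparisons between groups moved by up to 0.62, and 0 of 52 changed sign.

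The fits were tested on simulated data, with independent normal noise of each gene's fitted spread around the real means and known changes added. Each comparison was drawn in a single run, with 67 genes changed by 0.5, 67 by 1 and 66 by 2. The change of DMSO over time was not simulated. Of genes changed by 1 on the log2 scale, the fit called 64.2% at HT29 day 1 (12675 genes), 79.1% at day 3, 76.1% at day 8, 100% for the mean of the HT29 days, 14.9% for the difference between day 8 and day 1, 62.7% in Colo-205 (11575 genes) and 43.3% for the line difference (13659 genes). Of genes changed by 0.5, the size of many reported changes, it called 8.96%, 7.46%, 5.97%, 53.7%, 0%, 4.48% and 1.49% in the same order. The share of false calls was 4.31%, 3.94%, 3.97%, 3.43%, 2.70%, 9.02% and 1.05%. The Colo-205 fit thus exceeded the nominal 5% in this single run, with 11 of 122 calls false. At HT29 day 1 the simulation gave 116 calls, against 2862 in the data. Fewer changed genes make the adjusted threshold stricter, so these shares do not give the recovery in the real comparisons.

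The alternatives were the authors' processed values, no background correction, an offset of 50, normalization of each cell line separately, median scaling, no filter or a detection p under 0.05, other rules for probes, a trended robust variance, 1 fit of 18 arrays, a replicate block, no day block, other list tests, and leaving out each HT29 array or Colo-205 day in turn. Chosen after the data were seen were the maximum likelihood normexp and the fits without the last days. The correlation of effects between days or lines was taken across genes.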

Results

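RNA levels were measured on Illumina BeadChips in Matrigel cultures of HT29 and Colo-205, both established human colorectal cancer cell lines. Matrigel is a gel of basement membrane proteins in which the cells grow as 3D colonies. The cultures received 3 µM PLX4720, a RAF kinase inhibitor, or its solvent DMSO. The series concerns epithelial differentiation of colorectal cancer cells under RAF inhibition, followed over time. HT29 was sampled at days 1, 3 and 8 with 2 biological replicates per treatment and day (12 arrays). Colo-205 was sampled at days 1, 3 and 10 with 1 array per treatment and day (6 arrays). Treatment began on culture day 5, and the arrays labelled day 1 and day 3 were already treated. The days were therefore read as days of treatment, which is an inference from the labels.

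Between 18143 and 19606 of 47323 probes were above background on an array (38.3% to 41.4%), and the median raw intensity lay between 97.2 and 111. The 6 HT29 replicate pairs correlated at a Pearson r of 0.986 to 0.991 across genes, with an SD of the replicate difference of 0.30 to 0.38 on the log2 scale. The number of arrays limits the precision: the median standard error (SE) of a gene's log2 change was 0.18 at a single HT29 day, 0.10 for the mean of the HT29 days and 0.19 for the mean of the Colo-205 days. Changes below are log2 values of PLX4720 minus DMSO ± SE with adjusted p-values from limma. A gene not above background in one of the groups is given as a fold of at least the printed size.

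The day 1 comparison asked what the inhibitor did early in HT29, with 2 arrays against 2. Genes that ERK signalling induces were lower. DUSP6, a phosphatase that switches ERK off, fell by 2.53 ± 0.17 (adjusted p = 3.35e-05). The growth factor feedback gene SPRY4 changed by -1.74 ± 0.15 (adjusted p = 0.000121), the transcription factor ETV5 by -2.00 ± 0.11 (adjusted p = 1.09e-05), FOS by -2.15 ± 0.17 and the cyclin gene CCND1 by -1.84 ± 0.13. FOSL1, which encodes an AP-1 subunit, was not above background with PLX4720 and was at least 4.53-fold lower (adjusted p = 0.000202). The strongest rises were in SPINK1, a secreted trypsin inhibitor (4.85 ± 0.14, adjusted p = 7.68e-07), COXFA4L3 (4.43 ± 0.22), the lipocalin gene APOD (4.14 ± 0.22), the proton pump subunit gene ATP6V1B1 (4.01 ± 0.21) and SLC23A3 (3.68 ± 0.14). The deepest falls were in NNMT, which methylates nicotinamide (at least 11.2-fold lower, adjusted p = 9.36e-06), the pore-forming claudin CLDN2 (-3.35 ± 0.29), the neurotensin receptor NTSR1 (-2.88 ± 0.25), ADAM19 (-2.82 ± 0.14) and MYEOV (-2.62 ± 0.30).

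By group at day 1, 15 of 22 measured MAPK output genes fell (19 when adjusted over the list alone). The list's median was -1.20, with an adjusted p of 1.86e-13 in limma's camera test and 0.0125 with an estimated correlation. All 18 measured genes of ribosome biogenesis and MYC targets fell, in both adjustments (median -1.22, camera adjusted p = 1.74e-14). They included the spermidine synthase gene SRM (-1.84 ± 0.11) and the nucleolar protein gene NOP16 (-1.75 ± 0.16), and MYC itself fell by 1.49 ± 0.22. Of 17 glycolysis genes, 8 fell (9 adjusted over the list alone), led by hexokinase 2, HK2 (-2.23 ± 0.13), and the glucose transporter SLC2A1 (-1.37 ± 0.13). The glycolysis list had an adjusted p of 0.00104, and adjusted p = 0.218 with an estimated correlation. Of 18 interferon response genes, 13 rose in both adjustments, with IFI27 at 1.97 ± 0.24 and the antiviral GTPase MX1 at 1.73 ± 0.17 (median 1.07, adjusted p = 1.72e-07, and adjusted p = 0.21 with an estimated correlation). Among 4 measured markers of non-epithelial cells, the smooth muscle actin gene ACTA2 rose as well (1.47 ± 0.19). Of 32 cell cycle genes, 5 fell (2 adjusted over the list alone; median -0.24, adjusted p = 0.00449, and adjusted p = 0.325 with an estimated correlation). In all, 1499 genes were higher and 1363 lower among 12675 tested. Without the second PLX4720 replicate of day 1 the total of 2862 became 1857.

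At day 3 the same question gave lower MAPK output, glycolysis and ribosome genes. Some differentiation genes were higher, but no list of them held with an estimated correlation. DUSP6 fell by 2.21 ± 0.17 (adjusted p = 0.000109), HK2 by 2.16 ± 0.13 and SRM by 1.23 ± 0.11. TFF3, a goblet cell trefoil peptide, rose by 3.29 ± 0.32 (adjusted p = 0.000361), the membrane mucin MUC13 by 1.56 ± 0.15 and the adhesion molecule CEACAM6 by 1.69 ± 0.39 (adjusted p = 0.0194). The intestinal transcription factors CDX1 (at least 2.24-fold, adjusted p = 0.00412) and CDX2 (at least 1.75-fold, adjusted p = 0.0498) were higher than in DMSO, where neither was above background. The strongest rises were in SPINK1 (4.77 ± 0.14), the lipid flippase gene ATP10B (4.01 ± 0.22), CYP1A1, which oxidises aromatic compounds (3.95 ± 0.21), KLK12 (3.74 ± 0.22) and APOD (3.62 ± 0.22). The deepest falls were in the calcium-binding protein gene CALB2 (-3.94 ± 0.11, adjusted p = 4.45e-07), NNMT (at least 11.3-fold), ADAM19 (-3.07 ± 0.14), NTSR1 (-2.84 ± 0.25) and ANKRD37 (at least 5.75-fold).

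The day 3 lists that held with an estimated correlation were MAPK output, glycolysis and ribosome biogenesis. MAPK output had 12 of 22 genes lower (14 adjusted over the list alone; median -0.67, adjusted p = 1.22e-09, and 0.0317 with an estimated correlation). Glycolysis had 13 of 17 lower (14 adjusted over the list alone; median -0.79, adjusted p = 1.76e-10). Ribosome biogenesis and MYC targets had 14 of 18 lower (17 adjusted over the list alone; median -0.78, adjusted p = 1.22e-11). Of 21 enterocyte genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.46, adjusted p = 0.000218, and adjusted p = 0.0503 with an estimated correlation). Of 11 goblet cell genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), including SPDEF, a goblet cell transcription factor (1.39 ± 0.19), and FCGBP (1.62 ± 0.20). The goblet list's adjusted p of 0.00355 became an adjusted p = 0.102 with an estimated correlation. Stem cell and Wnt genes had 5 of 14 higher and 1 lower (7 and 1 adjusted over the list alone), with PROM1 at 2.19 ± 0.15 and the stem cell factor ASCL2 at 1.96 ± 0.16, while the Wnt antagonist DKK1 fell by 1.39 ± 0.29 (adjusted p of the list 0.00548, and adjusted p = 0.061 with an estimated correlation). Of 32 cell cycle genes, 10 fell (14 adjusted over the list alone; median -0.40, adjusted p = 7.42e-08, and adjusted p = 0.061 with an estimated correlation).

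Interferon response genes were again higher at day 3: 12 of 18 rose (15 adjusted over the list alone), led by IFI44L (1.79 ± 0.18; list adjusted p = 8.99e-08, and adjusted p = 0.0716 with an estimated correlation). MHC class I genes had 4 of 11 higher (9 adjusted over the list alone), such as the proteasome subunit PSMB9 (1.13 ± 0.22; list adjusted p = 8.1e-05, and adjusted p = 0.0503 with an estimated correlation). NF-kB and chemokine genes had 3 of 10 higher in both adjustments, with the chemokine CCL20 at 1.47 ± 0.23 (list adjusted p = 0.0133, and adjusted p = 0.0716 with an estimated correlation). ER and amino acid stress genes had 2 higher and 6 lower of 13 (2 and 7 adjusted over the list alone), with the amino acid transporter SLC7A5 at -1.29 ± 0.21 (list adjusted p = 0.0414, and adjusted p = 0.327 with an estimated correlation). The direction of this list's median turned, to 0.0090, without a filter on dim probes or with a detection p under 0.05. Of 4 non-epithelial markers, ACTA2 rose (0.78 ± 0.19) and LUM was at least 1.49-fold higher (list adjusted p = 0.0312, and adjusted p = 0.102 with an estimated correlation). In all, 1135 genes were higher and 954 lower. The total of 2089 became 857 and 1007 without the first and second DMSO replicate of day 3, and 984 and 833 without the first and second PLX4720 replicate.

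At day 8, genes of glucose use and low-oxygen response were far lower with PLX4720 in HT29. COXFA4L2, a mitochondrial protein gene formerly named NDUFA4L2, was at least 173-fold lower (adjusted p = 8.9e-07). The glycolytic enzyme genes ENO2 and ALDOC changed by -4.66 ± 0.34 and -4.50 ± 0.18, HK2 by -3.59 ± 0.13 and SLC2A1 by -2.81 ± 0.13 (adjusted p = 4.22e-06). The lipoprotein lipase inhibitor ANGPTL4 gave -3.92 ± 0.27, the vasodilator peptide gene ADM -3.26 ± 0.17, NTSR1 -4.97 ± 0.25 and CALB2 -4.16 ± 0.11. The strongest rises were in CYP1A1 (4.90 ± 0.21, adjusted p = 2.42e-06), ADH1C (4.43 ± 0.18), ADH1A (4.23 ± 0.14), AKR1C2 (4.18 ± 0.30) and PAX4, an endocrine transcription factor (at least 12.9-fold, adjusted p = 1.43e-05). The alcohol dehydrogenase pair and AKR1C2 have near-identical paralogs, so which gene of each family was measured is uncertain.

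All 17 glycolysis genes fell at day 8 in both adjustments (median -1.71, adjusted p = 6.75e-21, and 0.015 with an estimated correlation), and so did 11 of 13 hypoxia response genes (12 adjusted over the list alone; median -2.21, adjusted p = 1.6e-15). GAPDH, also counted as a reference gene, fell by 1.01 ± 0.11, and ACTB, a cytoskeletal actin gene, by 0.45 ± 0.11. All 18 interferon response genes fell, in both adjustments, the reverse of day 1 (median -1.75, adjusted p = 3.7e-20, and 0.0206 with an estimated correlation), with IFITM1 at -3.69 ± 0.23 and ISG15 at -2.19 ± 0.14. MHC class I genes had 8 of 11 lower (9 adjusted over the list alone), including the peptide transporter TAP1 (-2.09 ± 0.21; median -1.08, adjusted p = 9.52e-09). Of 4 non-epithelial markers, LUM was higher (at least 1.59-fold) and ACTA2, CD68 and DCN did not pass (list adjusted p = 0.227). MAPK output had 12 of 22 lower and 1 higher (14 and 1 adjusted over the list alone; median -0.80, adjusted p = 1.59e-07). DUSP6 changed by -2.33 ± 0.17, ETV5 by -1.31 ± 0.11 and the urokinase receptor PLAUR by -2.64 ± 0.15, while values for EGR1 (0.34 ± 0.17, adjusted p = 0.241) and FOSL1 (-0.33 ± 0.22, adjusted p = 0.356) did not pass.

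Markers of intestinal cell types were mixed at day 8. Of 6 measured enteroendocrine genes, 5 rose in both adjustments (median 1.59, adjusted p = 5.42e-05, and 0.046 with an estimated correlation), including SCG5 (1.95 ± 0.19), NEUROG3 (1.23 ± 0.28) and INSM1 (at least 3.85-fold). CDX1 was at least 6.77-fold higher (adjusted p = 4.64e-05), CDX2 rose by 1.95 ± 0.25 (adjusted p = 0.000905), the tight junction gene CLDN1 by 2.14 ± 0.18 (adjusted p = 7.72e-05) and OVOL2 by 1.93 ± 0.19. CEACAM1 fell by 1.25 ± 0.12, TFF2 by 1.86 ± 0.19, and TFF1 was at least 5.09-fold lower. Enterocyte genes thus counted 6 higher and 4 lower of 21, in both adjustments (adjusted p = 0.342), and goblet genes 4 higher and 2 lower of 11 (5 and 2 adjusted over the list alone, adjusted p = 0.291). Cholesterol synthesis genes had 7 of 18 lower in both adjustments, with DHCR7 at -1.11 ± 0.11 (list adjusted p = 0.00271, and adjusted p = 0.0577 with an estimated correlation). Ribosome biogenesis genes had 4 of 18 higher, in both adjustments, such as ODC1, which makes polyamines (1.10 ± 0.14; list adjusted p = 0.027, and adjusted p = 0.0885 with an estimated correlation). In all, 930 genes were higher and 1093 lower. The total of 2023 became 1005 and 997 without the first and second PLX4720 replicate of day 8, and 1161 without the second DMSO replicate.

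**Figure D1:**
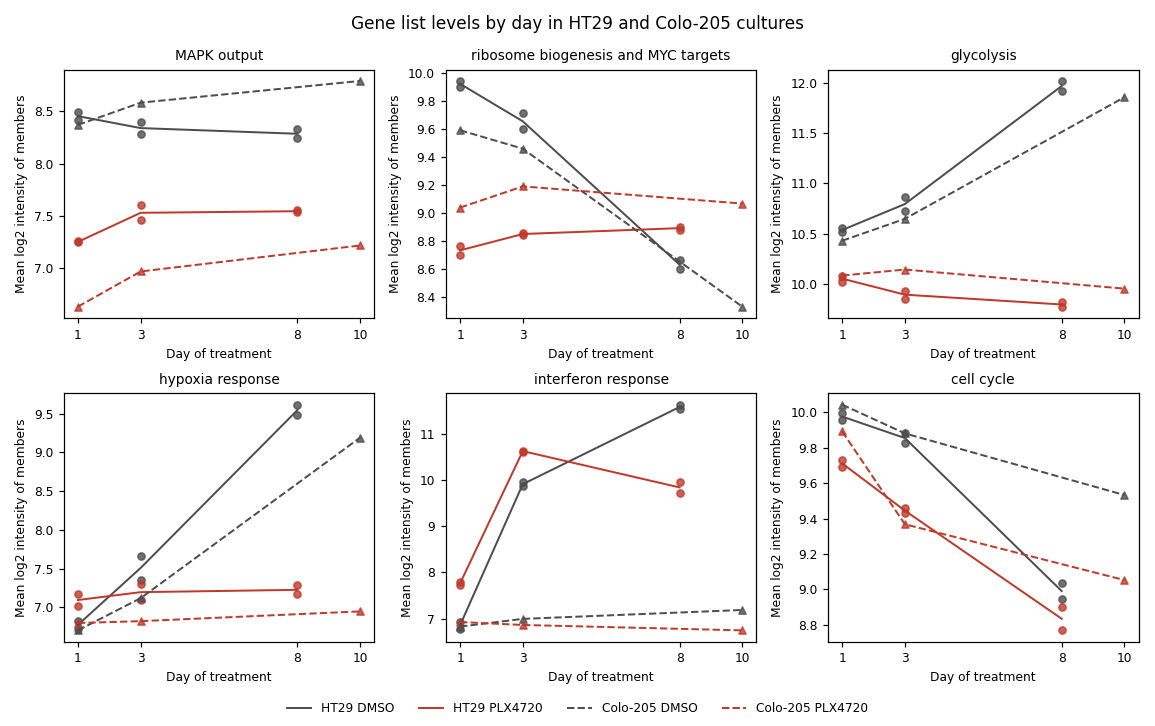
Mean log2 intensity (y axis) of the measured members of 6 gene lists against day of treatment (x axis). Points are single arrays (circles HT29, triangles Colo-205) and lines join group means: with DMSO the HT29 interferon list went from 6.86 at day 1 to 11.59 at day 8, and with PLX4720 from 7.76 to 9.84.

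The mean of the 3 HT29 days (6 arrays against 6) gave the average effect, which does not test whether the days shared it. CYP1A1 rose by 4.04 ± 0.12 (adjusted p = 1.17e-07), SPINK1 by 3.69 ± 0.08, SLC23A3 by 3.60 ± 0.08 and the paralogs ADH1C and ADH1A by 3.61 ± 0.10 and 3.51 ± 0.08, each in 6 of 6 pairs of arrays. NTSR1 (-3.56 ± 0.15, adjusted p = 6.35e-07), CALB2 (-3.31 ± 0.07), the growth factor gene FGF19 (-3.02 ± 0.11) and ADAM19 (-2.76 ± 0.08) fell, and NNMT was at least 9.81-fold lower, also in 6 of 6 pairs. The rule that named these genes required the same direction in every pair, so the 6 of 6 adds no support. FGF19 was at background with PLX4720 at day 1, so its mean is a fitted value without a bound. Of 22 MAPK output genes, 19 fell and 1 rose, in both adjustments (median -0.73, adjusted p = 5.34e-12, and 0.0153 with an estimated correlation). DUSP6 changed by -2.36 ± 0.10, FOS by -2.16 ± 0.10, IER3 by -2.03 ± 0.09, PLAUR by -1.86 ± 0.09, ETV5 by -1.69 ± 0.06, SPRY4 by -1.24 ± 0.09 and CCND1 by -0.98 ± 0.07. Of 17 glycolysis genes, 16 fell in both adjustments (median -0.97, adjusted p = 1.14e-13), with HK2 at -2.66 ± 0.07 and SLC2A1 at -1.92 ± 0.08. Of 18 ribosome biogenesis genes, 17 fell (18 adjusted over the list alone; median -0.52, adjusted p = 1.4e-09, and 0.0105 with an estimated correlation), although at day 8 alone the median was 0.14.

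Differentiation markers rose in part over the HT29 days. TFF3 rose by 2.24 ± 0.19 (adjusted p = 3.25e-05), AGR3 by 1.66 ± 0.17, MUC13 by 1.36 ± 0.09, CLDN1 by 1.22 ± 0.10 and CDX2 by 0.98 ± 0.14 (adjusted p = 0.000972), and CDX1 was at least 2.49-fold higher. The CDX2 mean is a fitted value without a bound, since CDX2 was at background in both groups of day 1 and in DMSO at day 3. CEACAM1 fell by 0.81 ± 0.07 and CLDN2 by 2.38 ± 0.17. The keratin KRT20 (0.03 ± 0.08, adjusted p = 0.805), E-cadherin, CDH1 (0.23 ± 0.09, adjusted p = 0.0991), LGR5 (0.35 ± 0.19, adjusted p = 0.191), CEACAM6 (0.28 ± 0.23, adjusted p = 0.394) and the proliferation marker MKI67 (-0.15 ± 0.16, adjusted p = 0.516) did not pass. Enterocyte genes had 9 of 21 higher and 1 lower (9 and 2 adjusted over the list alone; list adjusted p = 0.00924, and adjusted p = 0.133 with an estimated correlation). Enteroendocrine genes had 5 of 6 higher in both adjustments (list adjusted p = 0.00582, and adjusted p = 0.134 with an estimated correlation). Stem cell and Wnt genes had 6 of 14 higher and 1 lower (7 and 1 adjusted over the list alone), with PROM1 at 1.89 ± 0.09 and ASCL2 at 1.57 ± 0.09 (list adjusted p = 0.0118, and adjusted p = 0.129 with an estimated correlation). Goblet genes had 6 of 11 higher and 2 lower in both adjustments (list adjusted p = 0.0501). Epithelial junction genes split into 8 higher and 5 lower of 29 in both adjustments, with a list median of 0.05 (adjusted p = 0.508).

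Of 32 cell cycle genes, 17 fell over the HT29 days (20 when adjusted over the list alone), with the replication licensing gene CDC6 at -0.68 ± 0.11 and the cyclin CCNE1 at -0.69 ± 0.09 (list adjusted p = 4.75e-06, and adjusted p = 0.133 with an estimated correlation). The CDK inhibitor CDKN1B rose by 0.48 ± 0.07 (adjusted p = 0.000732), 1 other of 6 CDK inhibitors fell, and the list did not pass (adjusted p = 0.709). Hypoxia response genes had 10 of 13 lower and 1 higher in both adjustments (list adjusted p = 1.97e-05, and adjusted p = 0.144 with an estimated correlation). The fall came mostly from day 8: the median was 0.115 at day 1 with 3 higher and 1 lower (adjusted p = 0.3) and -0.169 at day 3 with 1 higher and 5 lower (adjusted p = 0.131), and without day 8 the mean turned to 0.038 (adjusted p = 0.829). Cholesterol synthesis genes had 9 of 18 lower and 3 higher (10 and 3 adjusted over the list alone; list adjusted p = 0.0372, and adjusted p = 0.144 with an estimated correlation). ER and amino acid stress genes had 7 of 13 lower and 1 higher (8 and 3 adjusted over the list alone; list adjusted p = 0.0245, and adjusted p = 0.237 with an estimated correlation). EGFR fell by 0.40 ± 0.08 (adjusted p = 0.00528) and ERBB3 rose by 0.58 ± 0.07 among 12 receptor tyrosine kinases and adaptors, of which 3 rose and 3 fell (3 and 4 adjusted over the list alone; list adjusted p = 0.881). The pro-apoptotic gene BMF rose by 1.00 ± 0.16 and PMAIP1 fell by 0.99 ± 0.10 (list of 14, 2 higher and 1 lower, 1 and 1 adjusted over the list alone, adjusted p = 0.964), while BCL2L11, which encodes BIM, gave -0.30 ± 0.22 (adjusted p = 0.328). CDC6 (PLX4720 at day 8), BMF (DMSO at days 1 and 3) and BCL2L11 (PLX4720 at day 3, DMSO at day 8) were at background in those groups, so their means are fitted values without a bound.

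The other lists did not pass for the mean of the HT29 days. Mesenchymal and invasion genes had 2 of 10 lower (adjusted p = 0.881), EGF family ligands 2 of 5 lower (0.214) and non-epithelial markers 2 of 4 higher (0.0501). Mitochondrial respiration had 5 of 17 higher and 1 lower (0.0501), and MHC class I 1 of 11 higher and 2 lower (0.614). These 5 counts were equal when adjusted over the list alone. Interferon response had 4 of 18 higher and 5 lower (5 and 5 adjusted over the list alone, 0.964), NF-kB and chemokines 4 of 10 higher (6 adjusted over the list alone, 0.112) and reference genes 1 of 8 higher and 4 lower (1 and 5 adjusted over the list alone, 0.0501). Median, mean and test differed in sign for the mesenchymal, apoptosis, receptor tyrosine kinase, interferon and MHC class I lists, and for none of the 63 list results past the threshold in any comparison. Over the HT29 days, 2138 genes were higher and 2024 lower, of which 227 and 126 by at least 2-fold.

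Days 1 and 3 shared 761 higher and 617 lower genes, where independent lists would share 134 and 103, and 4 genes went opposite ways. Days 1 and 8 shared 317 higher and 255 lower (110 and 118 for independent lists), and 222 genes went opposite ways. For the opposite counts the number for independent lists was not computed, so the 222 are not shown to exceed it. Across 12675 genes, which are not independent replicates, the effects of days 1 and 3 correlated at a Pearson r of 0.691, those of days 3 and 8 at 0.361 and those of days 1 and 8 at 0.203. All 3 days had 258 genes higher and 177 lower. No array was shared between the days.

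The difference between the day 8 and day 1 effects in HT29 was then tested itself. COXFA4L2 (-7.67 ± 0.38, adjusted p = 2e-05), the chloride channel gene CLIC3 (-5.08 ± 0.28), NDRG1 (-4.86 ± 0.26), ALDOC (-4.77 ± 0.26) and ANGPTL4 (-4.51 ± 0.38) had the most negative differences. For NDRG1, a hypoxia-induced gene, the effect went from 3.30 at day 1 to -1.56 at day 8. TMEM158 (3.95 ± 0.34), PAX4 (3.83 ± 0.33), HEPACAM2 (3.72 ± 0.24), the lysophospholipase ENPP2 (3.62 ± 0.29) and RGS4, which dampens G protein signalling (3.40 ± 0.16), had the most positive. COXFA4L2, TMEM158, PAX4, HEPACAM2, ENPP2, RGS4 and, below, FOSL1 and CDX2 were not above background in 1 or more of the 4 groups, so their differences are fitted values without a bound. All 18 interferon genes were lower in this difference, in both adjustments (median -2.36, adjusted p = 9.87e-22, and 0.0173 with an estimated correlation), with IFI27 going from 1.97 to -1.74. Of 18 ribosome biogenesis genes, 16 were higher (18 adjusted over the list alone; median 1.47, adjusted p = 3.02e-15). The ribosome list's mean level went from 9.92 at day 1 to 8.63 at day 8 with DMSO and from 8.73 to 8.89 with PLX4720. Hypoxia genes had 11 of 13 lower (12 adjusted over the list alone; median -2.80, adjusted p = 1.91e-13), glycolysis 14 of 17 (15 adjusted over the list alone; median -1.26, adjusted p = 1.05e-11) and MHC class I 9 of 11 (10 adjusted over the list alone; median -1.32, adjusted p = 5.86e-08).

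Within MAPK output, the effect on EGR1 differed by 2.30 ± 0.25 (adjusted p = 0.000566), FOSL1 by 1.87 ± 0.30, MYC by 1.79 ± 0.31, CCND1 by 1.43 ± 0.18, SPRY4 by 0.90 ± 0.22 and ETV5 by 0.69 ± 0.15, all from a fall at day 1 to a less negative value or, for EGR1 (0.34) and MYC (0.30), a value above 0 that did not pass at day 8. A less negative effect need not be a rise with PLX4720. From day 1 to day 8, the ETV5 arrays went from 8.5 and 8.7 to 7.7 and 7.7 with DMSO. With PLX4720 they went from 6.6 and 6.6 to 6.3 and 6.5. The CCND1 arrays went from 8.1 and 7.9 to 9.3 and 9.3 with PLX4720, and from 9.9 and 9.8 to 9.7 and 9.7 with DMSO. DUSP6 differed by 0.20 ± 0.24 (adjusted p = 0.618). The list had 7 of 22 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.0391, and adjusted p = 0.297 with an estimated correlation). The difference passed for CDX2 (1.80 ± 0.36, adjusted p = 0.00978) and CLDN1 (1.58 ± 0.25), and was -1.82 ± 0.22 for ASCL2. Enteroendocrine genes had 3 of 6 higher, in both adjustments (adjusted p = 0.00174, and adjusted p = 0.109 with an estimated correlation), and cholesterol synthesis 3 of 18 lower, in both adjustments (adjusted p = 0.0448, and adjusted p = 0.188 with an estimated correlation). In all, 894 differences were positive and 1129 negative. The total of 2023 became 1223 and 1287 without the first and second PLX4720 replicate of day 8.

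The untreated HT29 cultures changed over time as well. From day 1 to day 8 in DMSO, IFI27 rose by 7.87 ± 0.24 (adjusted p = 6.46e-08), IFI44L by 7.19 ± 0.18 and OAS2, which senses double-stranded RNA, by 7.17 ± 0.20, while COXFA4L2 was at least 163-fold and IFITM1 at least 160-fold higher. AKR1C2 (-3.51 ± 0.30), the aldehyde dehydrogenase ALDH3A1 (-3.32 ± 0.15, adjusted p = 9.47e-07), AKR1B15 (-3.30 ± 0.19) and AKR1B10 (-3.23 ± 0.22) fell, and the cystine transporter SLC7A11 was at least 7.53-fold lower. AKR1C2, AKR1B15 and AKR1B10 have near-identical paralogs within their own families, and which gene of each family was measured is uncertain. All 18 interferon genes rose (median 4.33, adjusted p = 1.98e-19, and 0.0218 with an estimated correlation), as did all 11 MHC class I genes (median 1.99, adjusted p = 7.53e-09), both also when adjusted over the list alone, with TAP1 at 3.37 ± 0.21 and PSMB9 at 3.54 ± 0.22. HLA-B, at least 50.4-fold higher, has close paralogs and is uncertain. Among non-epithelial markers ACTA2 rose by 1.01 ± 0.19. Cell cycle genes had 27 of 32 lower (29 adjusted over the list alone; median -0.89, adjusted p = 1.57e-11), such as PLK1 (-1.70 ± 0.18), and ribosome biogenesis genes 17 of 18 lower in both adjustments (median -1.24, adjusted p = 2.53e-10).

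Low-oxygen and glucose genes rose in DMSO too: 12 of 13 hypoxia genes in both adjustments (median 2.87, adjusted p = 1.36e-09, and adjusted p = 0.0612 with an estimated correlation), such as NDRG1 (5.66 ± 0.18), and 13 of 17 glycolysis genes (14 adjusted over the list alone; adjusted p = 1.24e-06, and adjusted p = 0.0558 with an estimated correlation). Goblet genes had 9 of 11 higher in both adjustments, with TFF3 at 4.25 ± 0.32 and FCGBP at least 21.4-fold (list adjusted p = 0.000106, and adjusted p = 0.0588 with an estimated correlation). Enterocyte genes had 12 of 21 higher (13 adjusted over the list alone; adjusted p = 0.000479, and adjusted p = 0.0558 with an estimated correlation), including KRT20 (0.38 ± 0.14, adjusted p = 0.0493). Receptor tyrosine kinases had 8 of 12 higher in both adjustments, such as ERBB3 (1.79 ± 0.12; list adjusted p = 0.000567, and adjusted p = 0.124 with an estimated correlation). Stem cell and Wnt genes had 6 of 14 higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.0662 with an estimated correlation). In all, 2784 genes rose and 2592 fell.

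**Figure D2:**
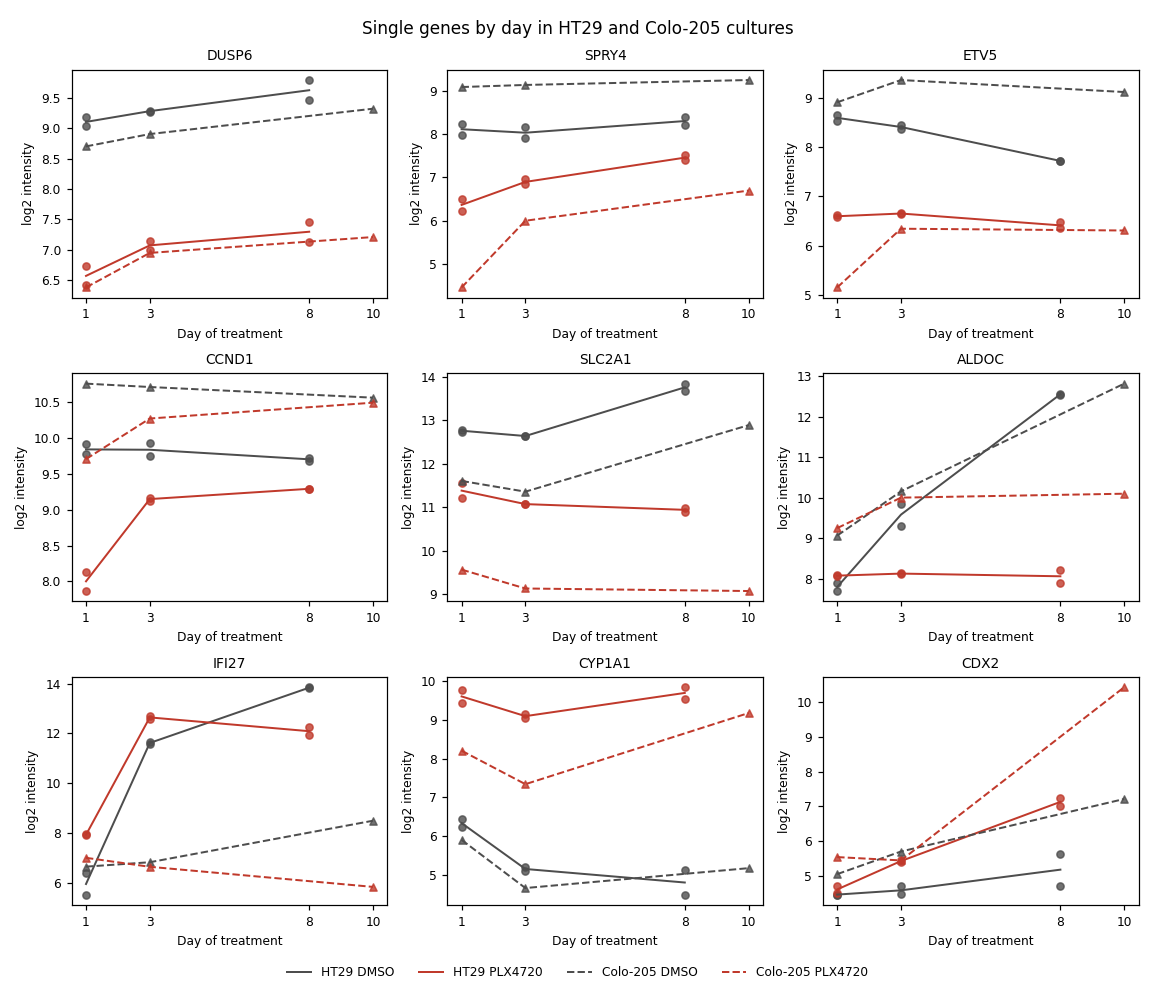
log2 intensity (y axis) of 9 genes against day of treatment (x axis), by cell line and treatment. Points are single arrays and lines join group means: DUSP6 with PLX4720 lay between 6.38 and 7.46 on every array, below all DMSO arrays, which lay between 8.70 and 9.79.

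In Colo-205 the mean of days 1, 3 and 10 asked whether the inhibitor acted on the same genes, with the days as the only replication (3 arrays against 3). ELAPOR1, formerly KIAA1324, was not above background in DMSO and was at least 44.2-fold higher with PLX4720 (adjusted p = 0.0178). The lipases and hydrolases CEL (4.29 ± 0.43, adjusted p = 0.0213) and CES1 (3.75 ± 0.48), the flippase gene ATP10B (3.96 ± 0.22) and the ribonuclease RNASE1 (3.71 ± 0.45) rose at 3 of 3 days. The phosphatase subunit gene PPP2R2C (-4.71 ± 0.37, adjusted p = 0.0126), CALB2 (-3.95 ± 0.47), the hyaluronan-binding protein gene CEMIP (-3.70 ± 0.47) and SPRY4 (-3.43 ± 0.39) fell, and the calpain CAPN8 was at least 14.5-fold lower, also at 3 of 3 days. The rule that named these genes required the same direction at every day, so the 3 of 3 adds no support. Of 23 MAPK output genes, 10 fell (18 when adjusted over the list alone). They included ETV5 (-3.21 ± 0.23, adjusted p = 0.0106), IER3 (-2.85 ± 0.18), FOS (-2.38 ± 0.21), DUSP6 (-2.13 ± 0.17, adjusted p = 0.0128) and FOSL1 (-2.05 ± 0.17), while CCND1 gave -0.52 ± 0.23 (adjusted p = 0.317) and MYC 0.04 ± 0.19 (adjusted p = 0.941). The list median was -1.77, with an adjusted p of 1.16e-19, and adjusted p = 0.325 with an estimated correlation. It was -0.90 with the authors' values and -0.91 without background correction.

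Of 17 glycolysis genes in Colo-205, SLC2A1 (-2.69 ± 0.37, adjusted p = 0.0385) and HK2 (-1.70 ± 0.24, adjusted p = 0.0421) fell, the only 2 in either adjustment (list adjusted p = 9.26e-07, and adjusted p = 0.781 with an estimated correlation). The other lists past the threshold had 0 single genes past it in limma over all genes, of 2018 genes at an unadjusted p under 0.05 in the whole comparison. They were cell cycle (32 genes, median -0.38, adjusted p = 6.19e-07, and adjusted p = 0.669 with an estimated correlation), EGF family ligands (4 genes, 3 lower adjusted over the list alone, median -0.94, adjusted p = 0.00418, and adjusted p = 0.669 with an estimated correlation), hypoxia (12 genes, median -0.57, adjusted p = 0.0203, and adjusted p = 0.781 with an estimated correlation), cholesterol synthesis (18 genes, median -0.34, adjusted p = 0.0317, and adjusted p = 0.781 with an estimated correlation) and ER stress (12 genes, 2 lower adjusted over the list alone, median -0.31, adjusted p = 0.0317, and adjusted p = 0.669 with an estimated correlation). The stem cell niche gene SMOC2 (2.92 ± 0.17) and the claudin CLDN15 (2.57 ± 0.19) rose. Of goblet cell genes, AGR3 rose (1.65 ± 0.25) and SPDEF fell by 1.18 ± 0.17, while CDX2 (1.15 ± 0.64, adjusted p = 0.416), KRT20 (0.44 ± 0.23, adjusted p = 0.392) and CDH1 (0.37 ± 0.16, adjusted p = 0.308) did not pass. The enterocyte, goblet and stem cell lists did not pass (adjusted p of 0.842, 0.075 and 0.571), nor did interferon response (0.283). Adjusted over the list alone, 2 enterocyte genes were higher and 2 lower, and 2 interferon genes were lower. BMF rose by 2.03 ± 0.29 (adjusted p = 0.0443).

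Colo-205 had 71 genes higher and 87 lower, all by at least 2-fold, among 11575 tested. The total of 158 became 38 without day 1 and 470 without day 10. Without day 3 it was 0 in limma, with 1023 genes at an unadjusted p under 0.05. By single days, which have no replicates and hence no test, the MAPK output median was -1.43, -1.45 and -1.75 at days 1, 3 and 10. The glycolysis median was -0.27, -0.42 and -1.73, the hypoxia median 0.15, -0.16 and -2.00, and the ribosome biogenesis median -0.67, -0.33 and 0.58. CDX2 gave 0.49, -0.26 and 3.22 on those days, CDX1 0.26, 0.43 and 4.03, and CLDN1 -0.73, -0.63 and 2.26. CEACAM1 (-0.63, -0.56 and -1.38) and CEACAM6 (-0.64, -2.37 and -1.68) were lower on each day, the goblet median was -0.13, -0.65 and -0.96, and the enterocyte median 0.23, -0.08 and -0.09. The interferon median was 0.07, -0.10 and -0.31.

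Whether the cell lines differed in their response was tested on all 18 arrays as the Colo-205 effect minus the HT29 effect. PPP2R2C (-4.70 ± 0.39, adjusted p = 1.29e-05), the retinaldehyde dehydrogenase ALDH1A3 (-3.77 ± 0.50), PIWIL1 (-3.73 ± 0.50), ADH1C (-3.68 ± 0.35) and CAPN8 (-3.64 ± 0.54) had the most negative differences. ALDH1A3 gave -1.17 in Colo-205 and 2.60 in HT29. ELAPOR1 (4.82 ± 0.62, adjusted p = 0.000522), CEL (4.14 ± 0.41), the stem cell marker OLFM4 (3.92 ± 0.79), CES1 (3.91 ± 0.40) and the gastric claudin CLDN18 (3.63 ± 0.41) had the most positive. Of these, ALDH1A3 and CEL were above background in every group, and the other 8 differences are fitted values that involve a group at background. Of 23 MAPK output genes, 8 had a lower effect in Colo-205 (10 adjusted over the list alone), among them SPRY4 (-2.19 ± 0.37, adjusted p = 0.00355) and ETV5 (-1.51 ± 0.23, adjusted p = 0.00152). Also among the 8 were DUSP4, at background in both HT29 groups, and EPHA4, at background in HT29 DMSO, and these 2 differences are fitted values. DUSP6 differed by 0.23 ± 0.18 (adjusted p = 0.599). The list median was -0.73, with an adjusted p of 7.91e-07, and adjusted p = 0.0719 with an estimated correlation. Its size depended on the processing: -0.22 with the authors' values, -0.23 without background correction, -0.36 with an offset of 50 and -0.46 with maximum likelihood normexp.

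Goblet genes had 3 of 11 negative line differences in both adjustments, such as TFF3 (-2.27 ± 0.51, adjusted p = 0.0215) and SPDEF (-1.97 ± 0.28; list adjusted p = 0.00674, and adjusted p = 0.397 with an estimated correlation). Ribosome biogenesis had 1 of 18 positive, NOP56, in both adjustments (list median 0.56, adjusted p = 0.00329, and adjusted p = 0.637 with an estimated correlation). In all, 212 differences were positive and 332 negative among 13659 genes tested, and each cell line was on a BeadChip of its own, so line and chip cannot be told apart. The total of 544 became 294 without the Colo-205 arrays of day 3 and 337 without those of day 10. The last day also differed, day 10 in Colo-205 and day 8 in HT29. In a fit of days 1 and 3 only, chosen after the data were seen, 530 genes passed. Of the 544 genes, 314 passed there in the same direction.

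The effects in the HT29 and Colo-205 means correlated at a Pearson r of 0.463 and a Spearman rho of 0.420 across 10911 genes tested in both, with the same sign in 65.4%. Genes are not independent replicates and no p is given. No array was shared between the lines. Both lines had 41 genes higher (10.3 for independent lists) and 49 lower (13.3 for independent lists), and 8 genes passed in opposite directions. For the opposite count the number for independent lists was not computed, so the 8 are not shown to exceed it. Those 8 were named after their values were seen: ACY3, ALDH3A1, KYNU, MT2A, MYOF and SPDEF rose in HT29 and fell in Colo-205, and MX2 and ZNF91 did the reverse. The line difference itself passed for all but MX2 (adjusted p = 0.0935). MYOF, a membrane repair protein gene, gave 0.52 ± 0.13 and -2.90 ± 0.20 (adjusted p of the difference 3.63e-06), and the metallothionein MT2A, which has close paralogs and is uncertain, 0.62 ± 0.10 and -1.77 ± 0.24.

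**Figure D3:**
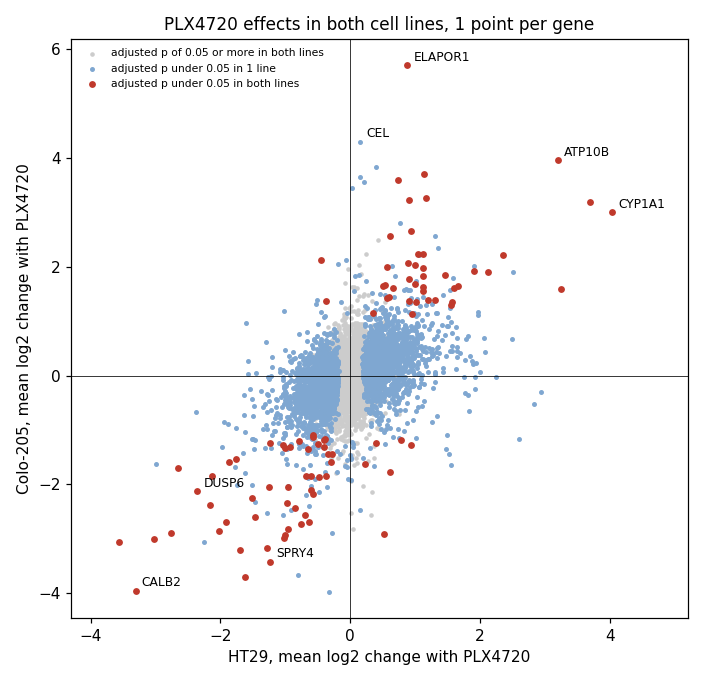
Mean log2 change with PLX4720 in HT29 (x axis) against that in Colo-205 (y axis), 1 point per gene for 10911 genes. Colours mark genes past an adjusted p of 0.05 in neither, 1 or both lines; CYP1A1 and ATP10B lie high in both and CALB2 low in both (-3.31 in HT29 and -3.95 in Colo-205).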

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

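The tests for RNA of immune or stromal cells, for swapped labels and for a general delay, and the splits with the day balanced, were chosen only after the result was seen.

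The PLX4720 effect in HT29 differed between day 8 and day 1 for 2023 genes in limma. This count fell to 1223 without the first and 1287 without the second PLX4720 replicate of day 8. The median differences of the lists past the threshold were -2.36 for interferon response, -1.32 for MHC class I, -2.80 for hypoxia response, -1.26 for glycolysis, 1.47 for ribosome biogenesis and MYC targets, 0.16 for MAPK output, 1.21 for enteroendocrine cell and -0.37 for cholesterol synthesis. With an estimated correlation the last 3 gave an adjusted p of 0.297, 0.109 and 0.188. Genes with a negative difference were COXFA4L2 (-7.67), CLIC3 (-5.08), NDRG1 (-4.86), ALDOC (-4.77), ANGPTL4 (-4.51), ASCL2 (-1.82) and SLC2A1 (-1.44). Genes with a positive difference were TMEM158 (3.95), PAX4 (3.83), HEPACAM2 (3.72), ENPP2 (3.62), RGS4 (3.40), EGR1 (2.30), FOSL1 (1.87), CDX2 (1.80), MYC (1.79), CLDN1 (1.58), CCND1 (1.43), EREG (1.26), SPRY4 (0.90) and ETV5 (0.69). COXFA4L2, TMEM158, PAX4, HEPACAM2, ENPP2, RGS4, FOSL1, CDX2 and EREG were not above background in 1 or more groups, so their differences are fitted values without a bound.

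Interferon response genes were higher with PLX4720 at day 1 in HT29 (adjusted p = 0.21 with an estimated correlation) and lower at day 8, and MHC class I genes were lower at day 8 without a call at day 1 (adjusted p = 0.149). RNA of immune or stromal cells would need their markers to fall at day 8, and the 4 measured markers had a median change of 0.24 (DCN -0.13, CD68 0.18, ACTA2 0.30, LUM 0.94). LUM was at background in DMSO at day 8, so its 0.94 is a fitted value and it could not show a fall. Only DCN, CD68 and ACTA2 remain, whose changes did not pass, and so few markers cannot decide on this explanation. Swapped day 8 labels were argued against by MAPK output, where the highest PLX4720 array lay at -0.69 from the lowest DMSO array. Over the other normalizations the interferon difference stayed at or below a median of -2.07. Swapped labels and the normalization were thus argued against, while RNA of immune or stromal cells was not decided. With the inhibitor, interferon genes were at 7.76, 10.63 and 9.84 on the log2 scale at days 1, 3 and 8. These levels were higher than DMSO at first and lower after DMSO rose on (6.86, 9.91 and 11.59). This course may be biological, as a hypothesis found and tested on the same arrays.

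Hypoxia response and glycolysis genes were lower with PLX4720 at day 8 in HT29. The normalization was argued against, since the higher of the medians stayed at or below -1.62 over the others. For a general delay, 21 goblet and enterocyte genes that rose with time in DMSO had a median day 8 change of -0.026 (SE 0.36), 7 higher and 6 lower. The DMSO day 8 arrays that chose them were also subtracted here, which lowers this value. At day 3, mean list levels with PLX4720 and DMSO were 6.8 and 6.0 for goblet and 6.8 and 6.2 for enterocyte genes. Cell cycle genes, which fell with time in DMSO, were at 9.4 and 9.9. These levels argue against a delay of these lists. Interferon and MHC class I genes, which also rose in DMSO, were lower at day 8. A delay of part of the genes, such as hypoxia and glycolysis, stays open. Mean hypoxia levels at days 1, 3 and 8 were 6.8, 7.5 and 9.5 with DMSO and 7.1, 7.2 and 7.2 with PLX4720. Glycolysis went from 10.54 at day 1 to 11.97 at day 8 with DMSO, and from 10.05 to 9.80 with PLX4720. Both lists thus rose in DMSO and stayed near their day 1 level with PLX4720. That the inhibitor opposed this late change stays open too, since a delay of these genes could give the same levels. Across all genes, the day 8 effect and the DMSO change from day 1 to day 8 correlated at -0.268 and -0.318. These were computed with separate DMSO day 8 arrays and do not test the hypoxia and glycolysis lists themselves. The colonies' size and oxygen supply were not measured here, and no biological explanation could be separated from a delay of these genes or an opposed change.

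The effect differed between Colo-205 and HT29 for 544 genes, and for 294 without the Colo-205 arrays of day 3 and 337 without those of day 10. The lists past the threshold had median differences of -0.73 for MAPK output, -0.47 for goblet cell and 0.56 for ribosome biogenesis, with an adjusted p of 0.0719, 0.397 and 0.637 with an estimated correlation. Genes with a negative difference were PPP2R2C (-4.70), ALDH1A3 (-3.77), PIWIL1 (-3.73), ADH1C (-3.68), CAPN8 (-3.64), TFF3 (-2.27), SPRY4 (-2.19) and ETV5 (-1.51). Genes with a positive difference were ELAPOR1 (4.82), CEL (4.14), OLFM4 (3.92), CES1 (3.91) and CLDN18 (3.63). Except for ALDH1A3, CEL, TFF3, SPRY4 and ETV5, these are fitted values that involve a group at background.

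The MAPK output list had a lower median effect in Colo-205 than in HT29, with 8 of 23 members past the threshold, others such as MYC at 0.79 (adjusted p = 0.369), and an adjusted p = 0.0719 with an estimated correlation. Probes near background in HT29 could give such a difference, and the 13 members with a DMSO mean above 8 on the log2 scale in both lines had a median of -0.38 (SE 0.49, range -2.19 to 0.79). Of the 8 members past the threshold, ETV5, IER3, PHLDA1, SPRED1 and SPRY4 were among these 13, and DUSP4, EPHA2 and EPHA4 were not. Members detected on every array gave -0.50 (adjusted p = 0.00272) and the whole list -0.23 without background correction, so this explanation stays open for the list as a whole. A BeadChip effect cannot be told apart from the line, since 0 lines were measured on both chips. A difference between the cell lines themselves stays open and untested beyond this.

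Other splits of the arrays were counted for each comparison with at least 3 arrays in a group. For the HT29 mean, fitted with day as a block, the real split gave 2783 genes and was the only 1 of 100 splits, drawn from 462, to reach that count. The highest other split gave 1 gene. Other splits mix treated and untreated arrays, so a real effect widens their spread and keeps their counts low. Chance is thus an unlikely explanation, but 100 splits do not exclude it. For Colo-205, 10 splits are too few for a share under 0.05. The real one gave 158 genes and the highest other 0 in limma, with 2018 genes at an unadjusted p under 0.05 in the real split, and the real count was 38, 0 and 470 without days 1, 3 and 10. The count of 0 without day 3 went with 1023 genes at an unadjusted p under 0.05. For the line difference, 2 of 84 splits of the PLX4720 arrays reached the real 544. The other one gave 1384 genes and put the Colo-205 array of day 10 with both HT29 arrays of day 8, which points to a structure of the last days, so these splits are not of exchangeable arrays. Among the 27 splits with 1 array from each time, only the real one reached 544 and the highest other gave 1. These splits were chosen after the others had been seen. Every other split among them mixes the lines, so a real line difference widens its spread and lowers its count. Chance is therefore not excluded for the line difference.

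Of 6462 probes with no symbol listed, 805 passed the threshold for the mean of the HT29 days (12.5%), 426 higher and 379 lower, against 4452 of 17033 named probes (26.1%).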

How the results depend on the processing

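The maximum likelihood normexp and the fits without the last days were chosen only after the result was seen. Under the alternatives 172 counts of genes stayed within 1.5 times the reported one and 23 moved. Of these, 75 and 15 came from leaving out an array or day, which often lay outside the groups compared. Leaving out any array of HT29 day 3 moved the day 3 count, to between 833 and 1007. Among list results past the threshold, 1556 kept direction and threshold, 93 kept only the direction and 3 reversed. Among genes past the threshold the numbers were 13141, 937 and 3, with 6252 of the first and 686 of the second from leave-out fits. The Colo-205 count of 158 became 464 with the authors' values, 456 without background correction, 448 with an offset of 50, 253 with median scaling, 304 with maximum likelihood normexp, 18 without a filter, 543 with a trended robust variance and 2266 with 1 fit of 18 arrays, where single Colo-205 days are assumed to vary like HT29. The correlation of the lines' effects, 0.463, became 0.372 without a filter, 0.396 with 1 fit of 18 arrays and 0.559 over genes past the threshold in at least 1 line. With an estimated correlation the MAPK output medians of -1.77 in Colo-205 and -0.73 for the line difference had an adjusted p of 0.325 and 0.0719. The ER stress list of HT29 day 3 reversed to 0.0090 without a filter and with a detection p under 0.05. Without day 8, the HT29 mean reversed for IFITM1 (0.70, adjusted p = 0.0107), RIGI (0.14), TAP1 (0.28) and the hypoxia list (0.038), the last 3 not past the threshold. The cause was not tested.

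Leaving out single arrays or days gave 1857 to 3118 genes at HT29 day 1, 833 to 2290 at day 3, 997 to 2043 at day 8, 3290 to 4111 for their mean, 1223 to 2138 for day 8 minus day 1, 4121 to 5323 for DMSO over time, 0 to 470 for Colo-205 (limma, 1023 genes at an unadjusted p under 0.05 where it was 0) and 294 to 561 for the line difference. The lowest counts came without the second PLX4720 replicate at days 1, 3 and 8, without the first PLX4720 replicate of day 8 for day 8 minus day 1, and without day 3 for Colo-205 and the line difference. MAPK output medians ranged from -0.81 to -0.70 in HT29, -1.80 to -1.45 in Colo-205 and -0.82 to -0.66 for the line difference. Processing moved them further: in that order to -0.60, -0.90 and -0.22 with the authors' values, to -0.59, -0.91 and -0.23 without background correction and to -0.68, -1.32 and -0.36 with an offset of 50. A lone array was assumed to vary like the other groups. With the replicate number as a block the counts were 2956, 2174, 2099, 4342, 2114 and 5541 for the HT29 comparisons in that order and 500 for the line difference, the MAPK output medians were -0.73 in both, and 15 of 564 gene calls were lost. Same-numbered arrays did not deviate together (15 pairs of groups, correlations of -0.02 to 0.13, 2 over 0.1), so the numbers were not read as pairs. The BeadChip as a block was not run, since each chip held 1 line. Probes tested on their own gave counts only. Signal over background limits the folds of dim genes.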

Other observations

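Which genes entered the NRF2 and aryl hydrocarbon receptor tests below was chosen only after AKR1B10, AKR1B15, AKR1C2, ALDH3A1, SLC7A11 and CYP1A1 had been seen to change. Those genes were left out of the lists. The p-values of these tests come from limma's camera, which is model-based and not an exact test at this number of arrays, and are not adjusted for the number of comparisons.

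In untreated HT29 cultures, genes that NRF2 induces, a transcription factor of the antioxidant response, fell from day 1 to day 8. Of 10 measured targets other than those seen before, 9 fell (median -0.93, camera p = 1.25e-05 in limma, and p = 0.0845 with an estimated correlation). GCLM, which makes glutathione, was taken out of the list after the test had been run with it, because its change had been seen. With GCLM, 10 of 11 fell (median -0.95, p = 2.25e-06, and p = 0.0774 with an estimated correlation). As a hypothesis, the fall of AKR1B10, AKR1C2 and ALDH3A1 over time may reflect lower NRF2 activity. With PLX4720 at day 8, AKR1C2 (4.18) and ALDH3A1 (2.09) rose. There the 10 targets had 3 higher and a median of 0.19 (camera p = 0.0972 in limma, and p = 0.463 with an estimated correlation). With GCLM, 4 of 11 were higher (median 0.27, p = 0.0413, and p = 0.394 with an estimated correlation). The aldo-keto reductases have near-identical paralogs and are uncertain.

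CYP1A1 rose with PLX4720 in HT29, and a candidate explanation is activity of the aryl hydrocarbon receptor, which induces it. The 4 other measured targets had a median of 0.58 over the HT29 days (CYP1B1 1.06, UGT1A6 0.83, NQO1 0.33 and TIPARP -0.18), with 3 higher. TIPARP did not pass over all genes but was lower when adjusted over the list alone, and fell at day 8 (-0.50, adjusted p = 0.0253), which goes against the receptor. The camera p was 0.0469 in limma, and p = 0.193 with an estimated correlation. At day 1, where CYP1A1 was already higher by 3.27, 1 of the 4 was higher (p = 0.278, and p = 0.454 with an estimated correlation). In Colo-205 CYP1A1 rose by 3.00 while the same 4 genes had a median of 0.15 (p = 0.955), and the line difference gave -0.50 (p = 0.0113, and p = 0.0454 with an estimated correlation). A rise of the other targets beside CYP1A1 was not found there. NQO1 is also a target of NRF2, and UGT1A6 shares sequence with related genes and is uncertain.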
